A study of Homo sapiens with 18 samples.

How the data were processed

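The data were 3' messenger RNA libraries (QuantSeq) made from total RNA of XG1 and AMO1 cells. The labels give both as multiple myeloma lines. Cells were kept for 24 h in DMSO or in 100 nM or 1000 nM of the CDK7 inhibitor YKL-5-124, with 3 replicates in each of 6 groups, 18 libraries in all. The labels number the replicates but do not say whether these were separate cultures, so the p-values measure only the spread between the samples.

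Per the submitters' processing notes, reads were aligned with HISAT2 to hg19 and gene values were made with Cuffnorm. Versions were not given in the sources used here. The deposited values were FPKM for 26341 entries per library, of which 26249 were genes and 92 were ERCC spike-ins. Summed spike-in values were nearly equal between groups, with group means from 171365 to 184681 FPKM. The values therefore appear to have been rescaled to the spike-ins, a step inferred from the values and not described in the notes. The files held no zeros. Each library had a floor value between 0.0711 and 0.158 FPKM, and 5120 genes stood at the floor in all 18 libraries. The lowest value was 0.0444 FPKM. FPKM divides by gene length, although 3' libraries give about 1 read per transcript, so values of short genes are inflated and levels of different genes cannot be compared. Read depth per library is not given in the sources used here, and the FPKM give no counting error. The precision was taken from the replicates, whose Spearman correlations within groups ran from 0.934 to 0.974. Of the gene symbols, 22940 (87.4%) were in the current human name table. The authors' gene models were not in the material used here. No coordinates were therefore used, and overlaps between genes were taken by name from RefSeq (GRCh38.p14). Whether the counting used the strand of the reads is not given in the sources used here.

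Samples were grouped by line and dose from their labels. The comparisons, tests, filters, gene lists and most alternatives were chosen before the data were examined. Each line's 9 libraries were fitted together for the comparisons of each dose with DMSO and of the doses with each other. All 18 libraries were fitted together for XG1 against AMO1 in DMSO and for the difference between the lines' responses (XG1 minus AMO1). Values were used as log2(FPKM+1), for genes of at least 1 FPKM in at least 3 libraries of the fit. The fit was a linear model with moderated two-sided t-tests and a mean-dependent prior variance (limma 3.58.1, R 4.3.3; jsonlite 2.0.0 read the sample records). Benjamini-Hochberg adjusted p under 0.05 was the threshold. On this deposited scale a change is a change relative to the spike-ins. Because most genes moved together, each change is also given relative to the median gene, after division by median-ratio size factors (the relative scale).

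The gene lists were written from general knowledge of each pathway or cell type, and a list was tested where at least 5 members passed the filter: 26 lists in XG1 and 24 in AMO1. List tests used camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. They were repeated with the correlation estimated from the data, and that adjusted p is given beside them. A second planned list test, fry, asks whether the members of a list changed at all, without comparing them with other genes. Its values are given for some lists of XG1 at 1000 nM only, in the section on the processing. List tests between the doses, between the lines' responses and between the lines in DMSO were added after the data were seen. For each list the count of members that changed is given over all tested genes and with adjustment over the list alone. Genes named in the text were the members of a list with the smallest adjusted p or the largest change, the genes with the largest change in a comparison, and 10 genes named for every comparison: CDK7, CCNH, MNAT1, MYC, IRF4, E2F1, CDKN1A, MCL1, CCND1 and ABCB1. Many of the genes with the largest changes were small RNAs. At 1000 nM these were 10 of the 10 largest decreases in AMO1 and 9 of 10 in XG1, but 3 of the 10 largest increases in each line. Their median SE in the tests against DMSO was 1.54 in XG1 and 1.11 in AMO1, against 0.220 and 0.214 for protein-coding genes, so they are not named. The protein-coding genes with the largest changes that stand in no list were chosen after the values were seen, as were examples picked for differing between lines.

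The tests were tried on simulated data with the group sizes and spread of each comparison and 200 changed genes. At log2 changes of 0.5, 1 and 2 the share recovered was 1.49%, 37.3% and 87.9% for XG1 at 1000 nM, and 2.99%, 35.8% and 87.9% for XG1 at 100 nM. Between the XG1 doses the shares were 5.97%, 40.3% and 86.4%. For AMO1 at 1000 nM they were 2.99%, 32.8% and 95.5%, at 100 nM 1.49%, 26.9% and 92.4%, and between the AMO1 doses 1.49%, 35.8% and 90.9%. The difference between the lines' responses gave 1.49%, 17.9% and 75.8% at 1000 nM and 2.99%, 16.4% and 83.3% at 100 nM, and XG1 against AMO1 gave 5.97%, 56.7% and 95.5%. With 200 changed genes, log2 changes of 0.5 were therefore nearly always missed in the simulations. In most real comparisons far more genes were called, which loosens the adjusted threshold. In AMO1 at 1000 nM 7164 genes were called, of which 3831 changed by at least log2 1. The simulated shares therefore do not carry over to such comparisons. False calls in the simulations were 1.56% to 7.61% of all calls.

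The alternatives were other scalings (median-ratio factors, equal totals, spike-in factors), other added constants, other filters, robust variance, 1 fit of all libraries, protein-coding genes alone, replicate numbers as a block, a minimum fold and each library left out in turn. Counts were also compared with those of every other split of the same libraries into groups of 3. With 3 against 3 the smallest exact two-sided p is 0.1, and there are 10 splits. Every split other than the real one keeps most libraries of each group together, so its count is not one without a group difference. No library was left out. Alignment, splicing and sequence variants were not analysed here.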

Results

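The summed FPKM of all genes fell with dose of YKL-5-124 in both lines. The summed spike-ins were level, which rescaling to them would bring about by itself. In AMO1 the total was 1515077 ± 62531 FPKM in DMSO (mean ± SD, n = 3), 941623 ± 36244 at 100 nM (62.2% of DMSO) and 600616 ± 146062 at 1000 nM (39.6%). In XG1 it was 1315368 ± 103067, 1066006 ± 76543 (81.0%) and 964298 ± 67859 (73.3%). Every treated library lay under all 3 DMSO libraries of its line, which gives the smallest exact p possible with 3 against 3, 0.1. At 1000 nM AMO1 replicate 2 was lower (431965 FPKM) than replicates 1 and 3 (686266 and 683618). In XG1, 100 nM replicate 2 stood apart from the other libraries on component 2 (loading −0.82), which held 16.3% of the variance. The most abundant genes weigh heavily in such a sum, and the median tested gene changed less. Against DMSO it changed by log2 −0.77 in AMO1 and −0.15 in XG1 at 1000 nM. At 100 nM it changed by −0.35 in AMO1 and −0.15 in XG1. Because of the fall in total, changes are given on the deposited scale and, as relative values, against the median gene.

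**Figure D1:**
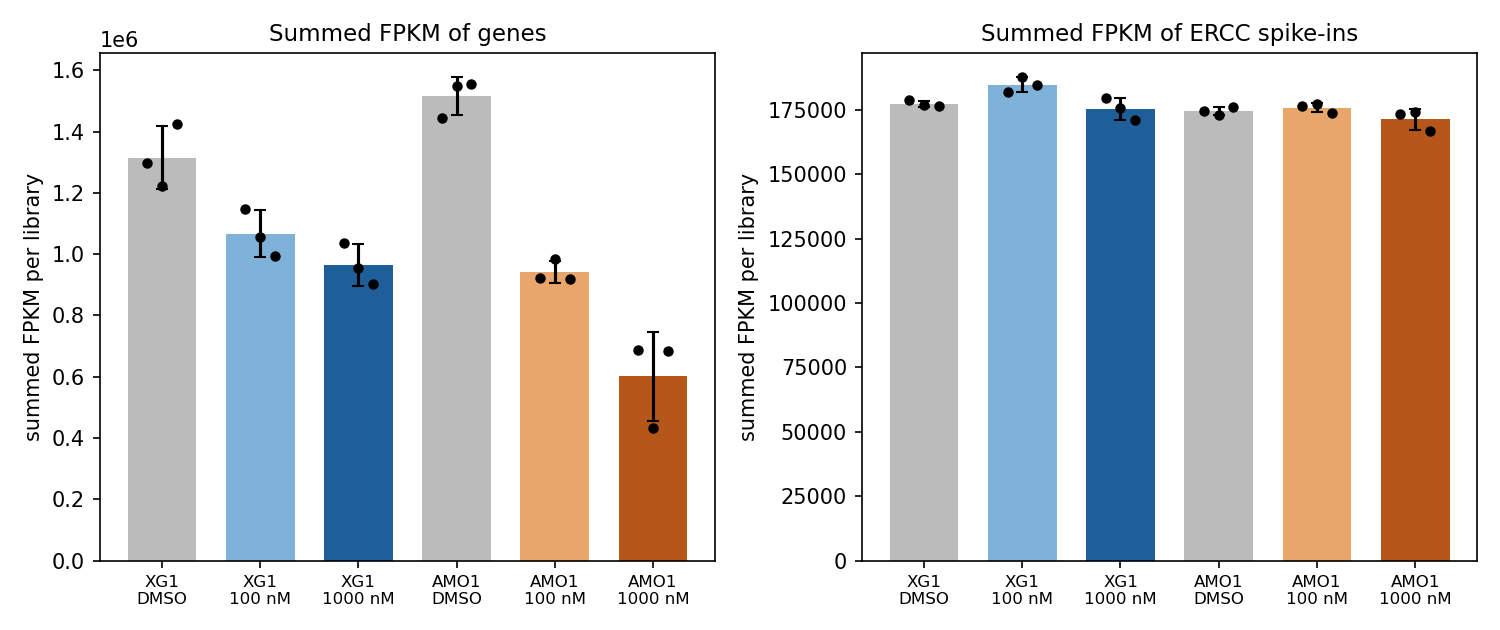
Summed FPKM of all genes and of the ERCC spike-ins by line and dose; bars are means with SD of 3 libraries and points are libraries. The gene sum fell to 39.6% of DMSO in AMO1 and to 73.3% in XG1 at 1000 nM, while the median tested gene changed by log2 −0.77 and −0.15. The spike-in sums were between 171365 and 184681 FPKM on average, a level that rescaling to them would bring about by itself.

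Before any inhibitor, the AMO1 libraries carried the genes of plasma cells, while the libraries labelled XG1 held most of these at low levels and carried globin genes. In DMSO the plasma cell surface proteoglycan SDC1 stood at 5067 ± 325 FPKM in AMO1 and 24.2 ± 12.4 in XG1 (n = 3 each). JCHAIN, which joins antibody units, stood at 1924 ± 102 and 5.46, the BAFF and APRIL receptor TNFRSF17 at 443 and 1.15, and the antibody-folding factor MZB1 at 873 and 3.62. IRF4, the transcription factor that plasma cells and myeloma cells need, was at 77.5 ± 6.13 FPKM in AMO1 and 0.533 ± 0.310 in XG1 (log2 difference −5.70, SE 0.18, adjusted p = 4.2e-14). In the other direction, the fetal globin gene HBG1 was at 1448 ± 113 FPKM in XG1 and 0.941 in AMO1, and the alpha globin gene HBA2 at 590.2 ± 17.2 and 0.329. The red cell surface protein GYPB was at 1302 ± 51.3 FPKM in XG1 and 0.481 in AMO1. HBG1 and HBA2 each have a near-identical copy, so their reads cannot be told with certainty from those of HBG2 and HBA1.

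Of 36 plasma cell genes, 4 were higher and 29 lower in XG1 (relative scale 1 and 32; adjusted p = 8.1e-17 over the lists, and adjusted p = 0.113 with an estimated correlation). All 22 tested genes of antigen presentation were lower in XG1 (adjusted p = 1.4e-21; 0.0602 with an estimated correlation). Among them HLA-DRA, a class II chain, was at 1.17 FPKM against 526, and its invariant chain CD74 at 0.997 against 448. Reads of HLA genes cannot be told apart with certainty. All 8 tested erythroid genes were higher in XG1 (adjusted p = 6.9e-06; 0.0602 with an estimated correlation). Endoplasmic reticulum chaperones and stress genes were lower in XG1 in 25 of 34 cases and higher in 1 (adjusted p = 7.8e-11, and 0.587 with an estimated correlation), with HERPUD1 at 24.2 against 203 FPKM. The integrated stress response list (6 higher, 22 lower of 33, adjusted p = 2.9e-06), the p53 targets (5 and 15 of 28, 3.2e-05) and the NF-kB targets (6 and 16 of 26, 0.00041) also lay lower. These 3 lists also had adjusted p = 0.587 with an estimated correlation. B cell genes lay lower (1 higher, 4 lower of 6, adjusted p = 0.0041, and 0.191 with an estimated correlation), with CD79B, part of the B cell receptor, at 0.501 FPKM in XG1 and 106 in AMO1.

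Single genes of other cell types were also on in the XG1 libraries. The myeloid integrin ITGAM was at 71.7 ± 9.68 FPKM and the T and NK cell receptor CD7 at 45.5 ± 11, against 0.168 and 0.0931 in AMO1. The myeloid list had 4 higher and 0 lower of 6 (adjusted p = 0.097, and 0.032 on the relative scale with 3 and 0, and 0.587 with an estimated correlation), the T and NK cell list 2 and 1 of 5, and the stromal list 1 and 1 of 5. Among the genes with the largest differences were the growth regulator DLK1 (1123 ± 62.5 in XG1, 0.337 in AMO1), the chemokine CCL3 (1.10 and 850.2 ± 72.3) and the cancer-testis antigen CTAG2 (3.20 and 1327 ± 72.0). UBE2C, which feeds ubiquitin to the anaphase machinery, was at 5.35 FPKM in XG1 and 1143 in AMO1. Across the genome 5754 genes were higher and 2538 lower in XG1 of 12792 tested (relative scale 4137 and 4279). The assignment of libraries to lines was taken from the labels, and no reference profile of either line was used here.

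**Figure D2:**
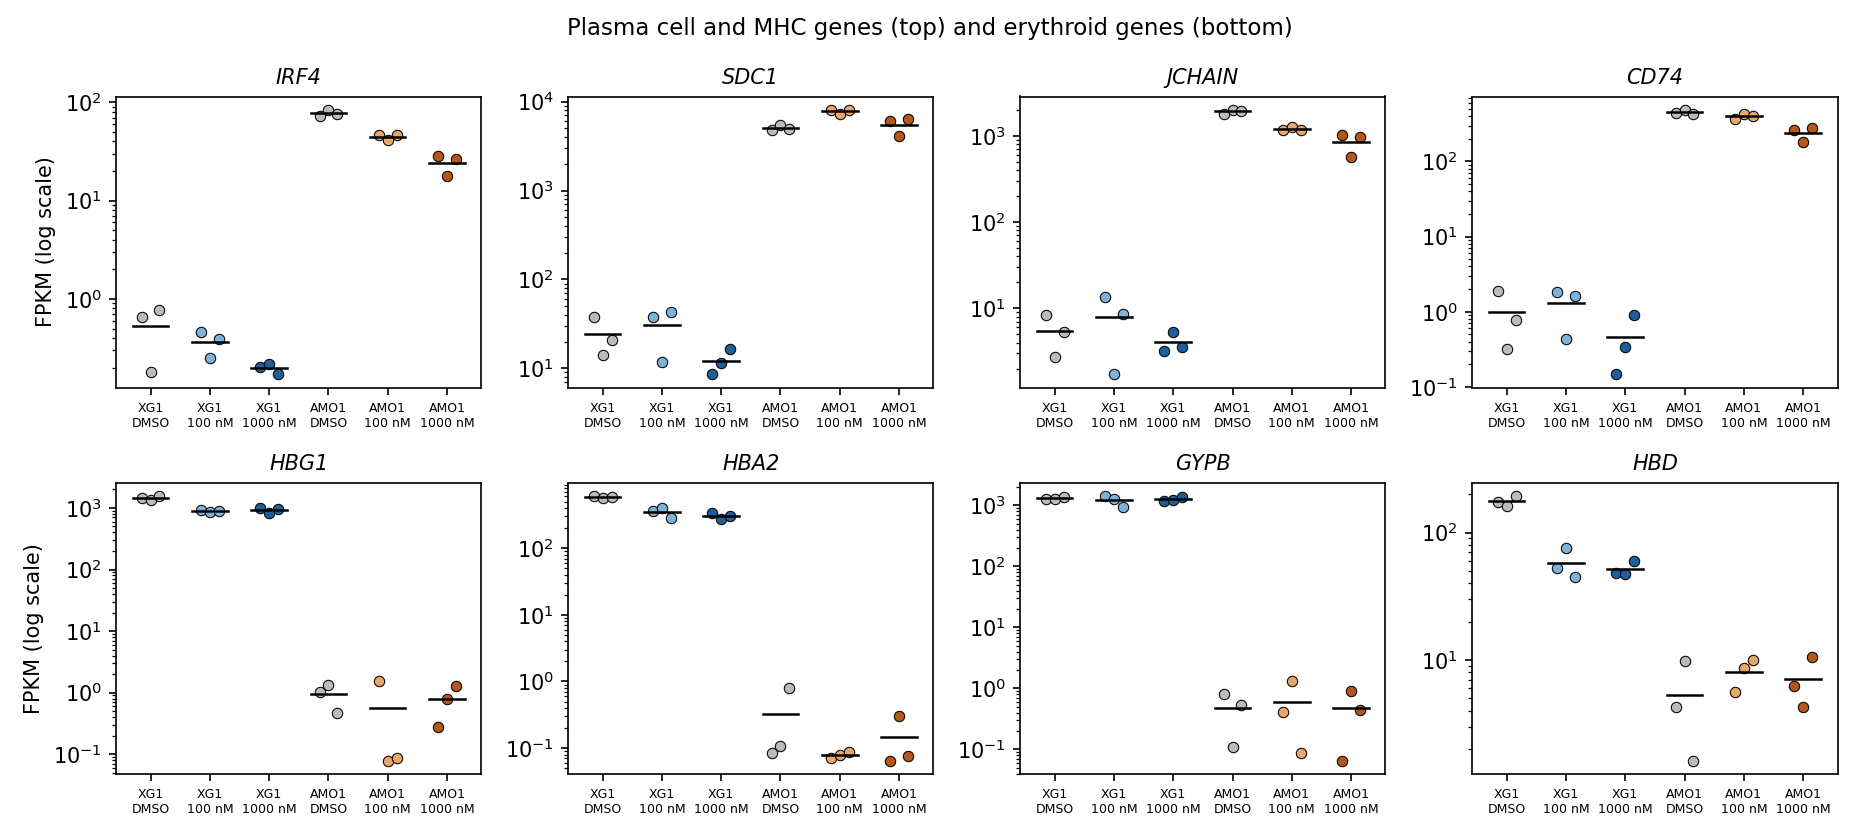
FPKM on log axes of plasma cell and antigen presentation genes (IRF4, SDC1, JCHAIN, CD74; top) and red cell genes (HBG1, HBA2, GYPB, HBD; bottom) by line and dose; points are libraries and bars are group means. IRF4 was at 77.5 FPKM in AMO1 and 0.533 in XG1 in DMSO, and HBG1 at 0.941 and 1448.

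In AMO1, 1000 nM YKL-5-124 lowered every tested gene of the replication and mitosis lists. RRM2, the ribonucleotide reductase subunit that makes DNA precursors, fell from 196 ± 9.91 to 5.84 ± 1.07 FPKM (log2 change −4.86, SE 0.19, adjusted p = 2.1e-09, n = 3 per group, relative −3.96). The mitotic kinase CDK1 fell from 106 ± 7.78 to 5.03 ± 1.17 (−4.16, SE 0.20, adjusted p = 4.2e-09, relative −3.27), and the DNA-untangling enzyme TOP2A from 195 ± 18.1 to 8.19 ± 1.89 (−4.43, relative −3.51). All 49 tested genes of DNA replication and all 50 of G2/M and mitosis fell, on both scales and with adjustment over each list alone (adjusted p = 3.9e-21 and 2.8e-22, both 0.517 with an estimated correlation). The origin-licensing genes CDT1 and CDC6 fell by log2 4.07 and 3.94, the helicase subunit MCM7 by 3.93, and the mitotic genes UBE2C and AURKB by 4.46 and 4.29. The histone gene HIST1H4C, which is made in S phase, went from 2200 to 112 FPKM, although reads of histone genes cannot be told apart with certainty. Homologous recombination genes followed, with 26 of 28 lower, 0 higher and 26 with adjustment over the list alone (relative scale 1 higher, 23 lower; adjusted p = 2.4e-06, and 0.819 with an estimated correlation). The nuclease EXO1, which trims broken ends, fell by log2 2.86 (SE 0.20).

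The amino acid stress genes fell nearly as far in AMO1. Of 31 genes of the integrated stress response, 30 fell and 0 rose, with 30 also over the list alone (relative scale 1 and 29; adjusted p = 2.9e-11, and 0.819 with an estimated correlation). CHAC1, which breaks down glutathione, fell from 62.2 ± 8.5 to 1.53 ± 0.09 FPKM (log2 −4.64, SE 0.19, relative −3.84), and the serine synthesis enzyme PSAT1 from 217 ± 16.7 to 9.45 ± 2.61 (−4.41, SE 0.22, relative −3.49). CTH, the last step of cysteine synthesis, fell by log2 4.0 (SE 0.19) and asparagine synthetase ASNS by 3.14 (SE 0.23). The growth program fell with them: 43 of 43 genes of MYC and ribosome biogenesis (relative scale 38 lower; adjusted p = 1.9e-09) and 58 of 58 ribosomal protein genes (37 lower relative to the median gene; adjusted p = 1.6e-05), both with adjusted p = 0.819 with an estimated correlation. The nucleolar genes NPM1 and NCL fell by log2 2.39 and 2.35, and RPL15, of the large subunit, from 1172 to 376 FPKM. Of 48 spliceosome genes 46 fell, 47 over the list alone (relative scale 2 higher and 34 lower; adjusted p = 2.2e-06, and 0.819 with an estimated correlation), including the U1 protein SNRPA from 256 to 36.5 FPKM. Glycolysis genes fell in 21 of 23 cases (relative 2 higher and 14 lower, adjusted p = 0.0014), with LDHA down by log2 2.68, and heat shock genes in 16 of 17 (relative 1 and 10, adjusted p = 0.0075), with the mitochondrial chaperonin HSPD1 down by 2.34. Both lists had adjusted p = 0.819 with an estimated correlation. Endoplasmic reticulum chaperones did not pass (0 higher and 26 lower of 34, but 8 and 8 on the relative scale, adjusted p = 0.24).

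The p53 targets split in AMO1 at 1000 nM. On the deposited scale 6 rose and 11 fell of 28, the same with adjustment over the list alone, whereas relative to the median gene 18 rose and 4 fell (adjusted p = 0.0014, 0.111 without the expression filter and 0.819 with an estimated correlation). The stress cytokine GDF15 rose from 55.0 ± 7.50 to 163 ± 36.1 FPKM (log2 1.53, SE 0.21, adjusted p = 3.3e-05, relative 2.49), and the quinone oxidoreductase TP53I3 from 2.16 to 7.49 (1.45, SE 0.23). The p53 antagonist MDM2 fell by log2 2.04 and the nutrient sensor SESN2 by 1.91. Outside this list, the decoy death receptor TNFRSF10D rose from 2.38 to 12.5 (1.99, SE 0.21) and the death activator PMAIP1 fell by log2 2.54. NF-kB targets likewise had 1 higher and 9 lower of 21 on the deposited scale but 11 higher and 2 lower on the relative scale (adjusted p = 0.022, 0.400 without the filter and 0.819 with an estimated correlation). Of 30 KRAB zinc finger genes 0 rose and 6 fell (2 over the list alone), while 10 rose and 1 fell relative to the median gene (adjusted p = 0.0023, 0.122 without the filter and 0.819 with an estimated correlation).

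Cholesterol genes had 1 higher and 20 lower of 24 in AMO1 at 1000 nM (relative 1 and 12; adjusted p = 0.046, and 0.819 with an estimated correlation), with INSIG1, a brake on sterol synthesis, down by log2 2.93. That list call was lost without 1000 nM replicate 1 (adjusted p = 0.0987) or replicate 2 (0.0598). Oxidative phosphorylation had 42 of 45 lower on the deposited scale (adjusted p = 0.042), but 5 higher and 7 lower relative to the median gene (adjusted p = 0.813). The deposited-scale call was lost without DMSO replicate 3 (0.121) and with an estimated correlation (0.819). Plasma cell genes did not pass as a list (26 of 35 lower and 1 higher, relative 12 higher and 10 lower; adjusted p = 0.47). The same held for the CDK7 complex and transcription genes (1 higher and 23 lower of 35, but 10 and 6 on the relative scale, adjusted p = 0.76), immediate-early genes (3 higher and 16 lower of 31, 0.063, but 16 and 5 on the relative scale, where the list passed, 0.027, and 0.819 with an estimated correlation) and BCL2 family genes (0 and 16 of 26, but 8 and 6 on the relative scale, 0.76).

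Genes that rose in AMO1 at 1000 nM despite the falling total were few. The histone gene HIST2H2BE, whose transcript can be polyadenylated, rose from 12.8 ± 1.00 to 60.5 ± 12.8 FPKM (log2 2.14, SE 0.21, adjusted p = 1.6e-06, relative 3.06), and the immediate-early gene FOS from 4.74 to 19.6 (1.7, SE 0.35). The mitochondrial nuclease ENDOG rose from 0.698 to 20 ± 12.1 (3.53, SE 0.35) and the copper chaperone SCO2 from 0.817 to 10.2 (2.70, SE 0.39). ENDOG overlaps SPOUT1, and SCO2 overlaps NCAPH2 and TYMP, and reads of overlapping genes cannot be told apart here. The same limit holds for other named genes that overlap a protein-coding gene, among them CDK7, CCNH, MDM2, TP53I3, CHEK1, TYMS, JUNB, GINS2 and HIST1H2BK. The largest protein-coding decreases outside the lists were the tubulin TUBB2B (log2 −4.56, SE 0.19; 72.2 to 2.14 FPKM) and the MYC target CDCA7 (−4.52, SE 0.23; 53.8 to 1.46). Over all 10503 tested genes 264 rose and 6900 fell (relative scale 2472 and 2569). No other of the 10 splits of these libraries gave more than 2 genes, though 10 are too few splits for a share under 0.05.

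**Figure D3:**
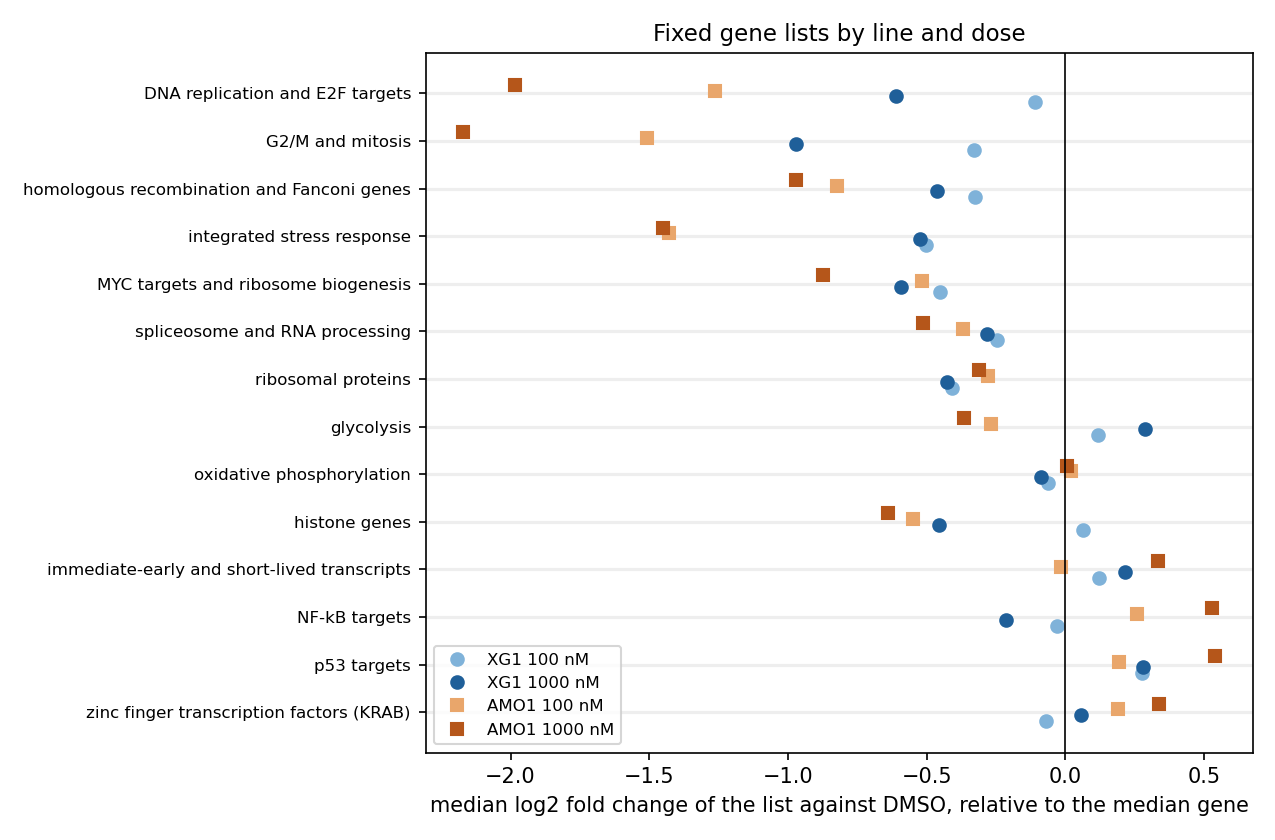
Median log2 change against DMSO, relative to the median gene, of 14 gene lists; circles are XG1, squares AMO1, light 100 nM and dark 1000 nM. At 1000 nM the G2/M list lay at −2.17 in AMO1 and −0.97 in XG1.

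**Figure D4:**
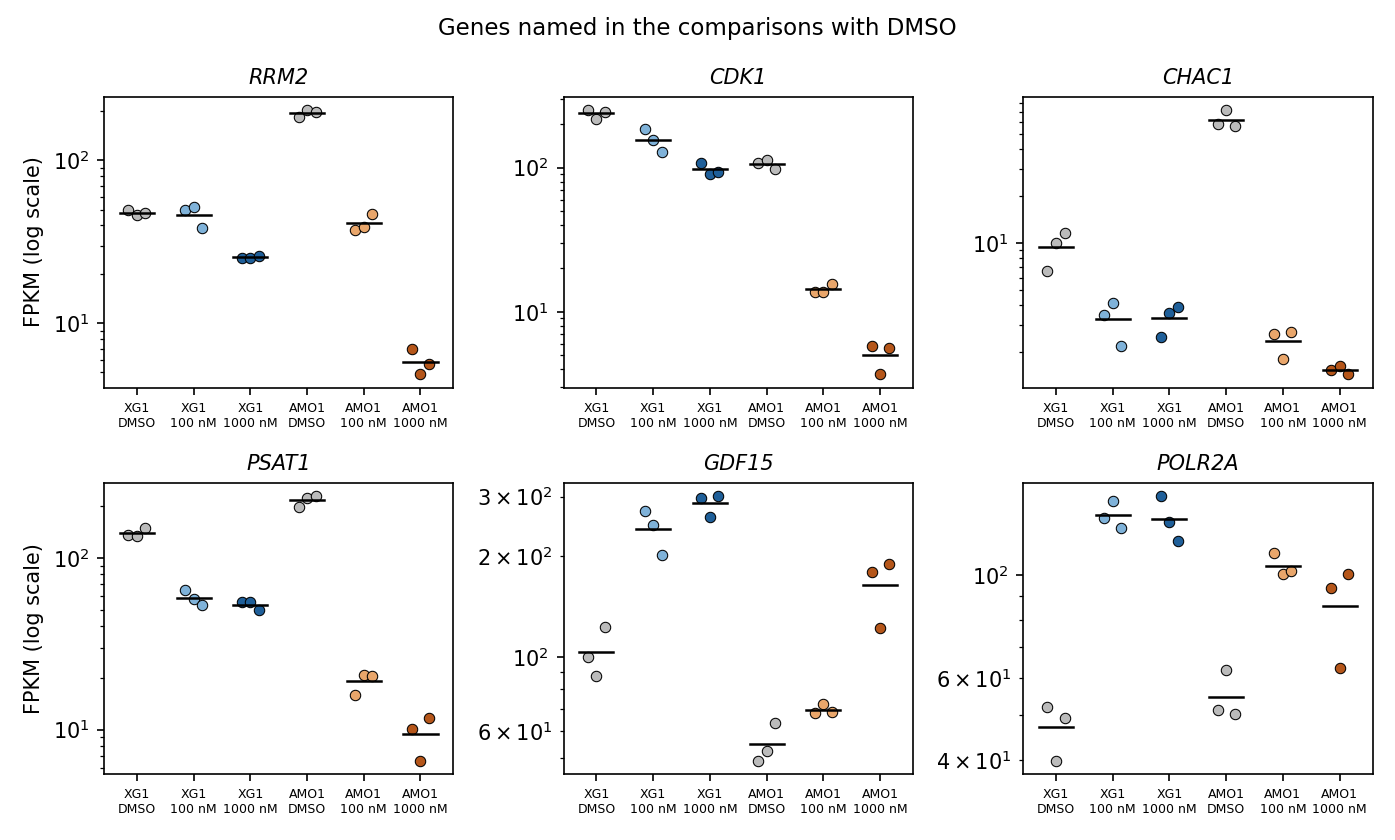
FPKM on log axes of RRM2, CDK1, CHAC1, PSAT1, GDF15 and POLR2A by line and dose; points are libraries and bars are group means. In AMO1 RRM2 fell from 196 to 5.84 FPKM at 1000 nM, and in XG1 from 47.9 to 25.4.

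At 100 nM division, stress response and growth genes fell in AMO1, while cholesterol genes (11 of 24 lower, adjusted p = 0.23) and oxidative phosphorylation (10 of 45 lower, 0.43) did not pass as lists. CHAC1 fell to 2.36 FPKM (log2 −4.23, SE 0.19, adjusted p = 1.7e-08, relative −3.79), CTH to 2.79 (−3.45, SE 0.19) and PSAT1 to 19.1 (−3.44, SE 0.22). The activin subunit INHBE, a target of the same stress pathway, fell from 28.9 to 1.09 FPKM (−3.84, SE 0.18). Of 31 genes of the integrated stress response 29 fell and 0 rose on both scales and over the list alone (adjusted p = 2.6e-19; 0.411 with an estimated correlation), among them ASNS (−2.37) and SESN2 (−2.0). All 49 replication genes and all 50 G2/M genes fell (relative 47 and 50; adjusted p = 1.1e-27 and 2.9e-33; both 0.245 with an estimated correlation). CDK1 fell to 14.3 ± 1.02 FPKM (−2.80, SE 0.20), TOP2A to 27.2 (−2.80, SE 0.21), CDT1 to 15.6 (−2.57, SE 0.18) and the helicase subunit MCM6 from 30.5 to 4.66 (−2.49, SE 0.22). Homologous recombination had 24 of 28 lower and 0 higher (relative 21; adjusted p = 3.9e-09; 0.465 with an estimated correlation).

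MYC and ribosome biogenesis genes fell in 36 of 43 cases in AMO1 at 100 nM (41 over the list alone, 30 relative, adjusted p = 8.5e-09), ribosomal protein genes in 46 of 58 (52 over the list alone, 32 relative; 1.3e-05) and spliceosome genes in 36 of 48 (relative 1 higher and 30 lower; 6.5e-07). These 3 lists had adjusted p = 0.838 with an estimated correlation. NPM1 fell by log2 1.55 (SE 0.21) and the splicing regulator HNRNPA1 from 272 to 77.3 FPKM (−1.81, SE 0.24). Smaller lists that passed were G1 genes (0 higher, 12 lower of 21, relative 0 and 8, adjusted p = 0.014), glycolysis (13 of 23 lower, relative 1 higher and 8 lower, 0.0091) and heat shock genes (9 of 17 lower, relative 7, 0.0091), again with 0.838 with an estimated correlation. NF-kB targets and interferon genes lay above the other genes, though their median members did not rise on the deposited scale (log2 −0.07 and −0.02). Of the NF-kB targets 2 rose and 1 fell of 21 (relative 8 and 1, adjusted p = 0.0078, and 0.0556 without the filter). Of the interferon genes 1 rose and 4 fell of 24, against 9 and 3 on the relative scale (adjusted p = 0.019). Both lists had 0.838 with an estimated correlation. KRAB zinc finger genes had 0 higher and 2 lower of 30 but 3 and 1 on the relative scale (adjusted p = 0.028, 0.069 on the relative scale and 0.838 with an estimated correlation). The p53 targets did not pass (3 higher and 8 lower of 28; adjusted p = 0.271), and the death activator BBC3 fell by log2 1.41 (SE 0.19).

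POLR2A, the largest subunit of RNA polymerase II and bearer of the tail that CDK7 phosphorylates, rose in AMO1 from 54.7 ± 6.82 to 105 ± 5.97 FPKM at 100 nM (log2 0.93, SE 0.21, adjusted p = 0.0057, relative 1.36). At 1000 nM it was 85.8 ± 20 (0.62, SE 0.21, adjusted p = 0.0196, relative 1.58, adjusted p = 7.3e-07). The deposited-scale call at 1000 nM was lost without DMSO replicate 1 (adjusted p = 0.0725) or 3 (0.0775), or without 1000 nM replicate 1 (0.0584) or 3 (0.0693). ENDOG and SCO2, with the overlaps given above, rose to 21.7 and 21.9 FPKM at 100 nM. In all 287 genes rose and 3099 fell at 100 nM (relative 1473 and 1781). The 3386 calls became 1812 without DMSO replicate 2 and 2167 without 100 nM replicate 1. No other of the 10 splits gave more than 4 genes, again too few splits for a share under 0.05.

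From 100 to 1000 nM the cell division genes of AMO1 kept falling. RRM2 went from 41.2 ± 4.88 to 5.84 ± 1.07 FPKM (log2 −2.63, SE 0.19, adjusted p = 1.7e-05, relative −2.16), while GDF15 rose from 69.7 ± 2.45 to 163 ± 36.1 (1.19, SE 0.21, adjusted p = 0.0048, relative 1.72). Of 49 replication genes 41 fell further (31 relative, 45 over the list alone; adjusted p = 2.3e-21), as did 39 of 50 G2/M genes (23 relative, 45 over the list alone; 1.1e-15). The p53 targets had 2 higher and 1 lower of 28, with 10 and 1 on the relative scale (adjusted p = 4.1e-08). These 3 lists had adjusted p = 0.793, 0.848 and 0.848 with an estimated correlation. Between the doses 22 genes rose and 2460 fell, against 175 and 439 on the relative scale, so most of that count followed the total. The 2482 calls became 764, 656 and 519 without 100 nM replicate 1, 2 and 3.

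In XG1 1000 nM lowered mitotic genes, by less than in AMO1. The mitotic kinase AURKB fell from 357 ± 38.1 to 80.7 ± 9.50 FPKM (log2 −2.13, SE 0.13, adjusted p = 7.4e-06, n = 3 per group, relative −1.95) and TOP2A from 317 ± 14.9 to 74.8 ± 6.90 (−2.07, SE 0.22, relative −1.89). Of 50 G2/M genes 44 fell and 0 rose, 47 over the list alone (relative 42, adjusted p = 2.3e-22, and 0.488 with an estimated correlation), including the kinetochore genes NDC80 (−1.87) and CENPF (−1.80). Of 50 replication genes 32 fell and 0 rose, with 1 higher and 42 lower over the list alone (relative 1 higher and 27 lower, adjusted p = 5.4e-13, and 0.488 with an estimated correlation), including CDT1 from 120 to 39.3 FPKM (−1.59, SE 0.14) and thymidylate synthase TYMS from 209 to 82.7 (−1.33, SE 0.18). Homologous recombination genes fell in 13 of 29 cases, 18 over the list alone (relative 14, adjusted p = 2.7e-06, and 0.488 with an estimated correlation), with the checkpoint kinase CHEK1 down by log2 1.44.

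Ribosome genes fell in XG1 as well. Of 58 ribosomal protein genes 49 fell and 0 rose, 55 over the list alone (relative 39, adjusted p = 1.1e-15, and 0.488 with an estimated correlation), with RPL6 from 796 to 249 FPKM (log2 −1.68, SE 0.20) and RPL23 from 10210 to 4657 (−1.13, SE 0.15). Of 44 genes of MYC and ribosome biogenesis 33 fell, 36 over the list alone (relative 28, adjusted p = 8.1e-14, and 0.488 with an estimated correlation), with the nucleolar GTPase GNL3 from 20.9 to 5.62 FPKM (−1.74, SE 0.26) and NCL from 468 to 198 (−1.24, SE 0.13). Of 32 integrated stress response genes 18 fell and 0 rose (relative 2 higher and 16 lower, adjusted p = 2.3e-06, and 0.488 with an estimated correlation). The serine synthesis enzymes PHGDH and PSAT1 fell by log2 1.48 and 1.37, ASNS by 1.39 and CHAC1 by 1.26. Spliceosome genes fell in 27 of 48 cases and rose in 1 (relative 3 and 20, adjusted p = 1.1e-06, and 0.672 with an estimated correlation), with SNRPA and HNRNPA1 each down by log2 1.27. Oxidative phosphorylation had 12 of 45 lower (adjusted p = 0.0063, 0.121 on the relative scale and 0.902 with an estimated correlation), with COX7C down by log2 0.76.

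GDF15 rose in XG1 from 103 ± 17.6 to 287 ± 22.1 FPKM at 1000 nM (log2 1.48, SE 0.15, adjusted p = 0.00022, relative 1.66), the p53-induced growth brake BTG2 from 10.2 to 36.9 (1.76, SE 0.16), and the RNA-binding p53 target ZMAT3 by log2 0.93 (SE 0.15). Of 24 p53 targets 4 rose and 1 fell, 6 and 1 over the list alone (relative 8 and 0, adjusted p = 0.0034, and 0.672 with an estimated correlation). Immediate-early genes had 5 higher and 2 lower of 33 (relative 9 and 2, adjusted p = 0.0063, and 0.722 with an estimated correlation), with JUNB from 34.8 to 83.1 FPKM (1.23, SE 0.13). POLR2A rose from 47.2 ± 6.39 to 132 ± 14.7 FPKM (1.47, SE 0.14, adjusted p = 0.00013, relative 1.65). The histone gene HIST1H2BK rose from 439 ± 15.8 to 1722 ± 264 FPKM (1.96, SE 0.12) while HIST1H4C fell from 3941 to 670 (−2.58, SE 0.18), and the histone list as a whole did not pass (6 higher and 7 lower of 25; adjusted p = 0.438). The neutrophil attractant CXCL8 fell from 68.3 ± 12.0 to 11.4 ± 4.54 FPKM (−2.55, SE 0.37, adjusted p = 0.0012).

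The red cell genes of XG1 fell at 1000 nM. The delta globin gene HBD went from 176 ± 16.5 to 52.0 ± 7.04 FPKM (log2 −1.74, SE 0.18, adjusted p = 0.00023, relative −1.56) and HBA2 from 590.2 to 307 (−0.95, SE 0.14, adjusted p = 0.0015, relative −0.76). HBG1 fell from 1448 ± 113 to 921 ± 78.0 (−0.65, SE 0.11, adjusted p = 0.0028, relative −0.47), a call lost in the fit of all 18 libraries (0.111) and with equal totals (0.105). As a list 4 of 8 erythroid genes fell and 0 rose (relative 1 and 4; adjusted p = 0.055). The entries HNRNPH2 and RPL36A-HNRNPH2 moved as mirror images, from 0.228 to 78.4 ± 12.4 FPKM and from 96.0 ± 14 to 0.480 ± 0.606. They overlap, and their sum changed by log2 −0.28. MEIG1, which overlaps DCLRE1C, was listed at the floor in DMSO and at 6.49 FPKM at 1000 nM (adjusted p = 0.0086). In all 436 genes rose and 1558 fell of 11810 (relative 1111 and 1208), and no other of the 10 splits gave more than 3, too few splits for a share under 0.05. The 1994 calls became 1197 and 1047 without DMSO replicates 1 and 3, and 1144 and 1179 without 1000 nM replicates 2 and 3.

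At 100 nM the ribosome and stress lists of XG1 had moved about as far as at 1000 nM, and the division lists had moved much less. RPL6 fell by log2 1.32 (SE 0.20) and RPL23 by 1.07 (SE 0.15), and 44 of 58 ribosomal protein genes fell with 0 higher (50 over the list alone, relative 33; adjusted p = 3.7e-14, and 0.727 with an estimated correlation). MYC and ribosome biogenesis had 24 of 44 lower (35 over the list alone, relative 19; adjusted p = 4.8e-11, and 0.727 with an estimated correlation), with GNL3 down by log2 1.54 and the ribosome assembly helicase DDX18 by 1.09. ASNS fell to 13.2 FPKM (−1.72, SE 0.17, adjusted p = 0.00022) and PSAT1 to 58.6 (−1.24, SE 0.13), and 16 of 32 integrated stress response genes fell with 0 higher (24 over the list alone, relative 12; adjusted p = 9.0e-08, and 0.727 with an estimated correlation). Spliceosome genes fell in 21 of 48 cases (relative 2 higher and 15 lower; adjusted p = 3.9e-05, and 0.866 with an estimated correlation), with HNRNPA1 down by log2 1.08. G2/M genes had 13 of 50 lower (relative 1 higher and 8 lower; adjusted p = 0.00034), replication genes 8 of 50 (relative 6; 0.0135, and 0.086 on the relative scale) and homologous recombination 5 of 29 (0.0061). These 3 lists had 0.866, 0.952 and 0.866 with an estimated correlation. The spindle checkpoint gene MAD2L1 fell by log2 1.04, the polymerase clamp PCNA by 1.13 and MCM6 by 1.02.

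The histone genes HIST1H2BK and HIST1H1C were among the gains in XG1 at 100 nM, from 439 ± 15.8 to 2954 ± 117 FPKM (log2 2.75, SE 0.12, adjusted p = 5.7e-07) and from 414 ± 65.9 to 1817 ± 171 (2.14, SE 0.14). The histone list had 9 higher and 4 lower of 25 (adjusted p = 0.0049, 0.084 on the relative scale and 0.727 with an estimated correlation) with a median change of −0.12, or 0.06 on the relative scale. POLR2A rose to 134 ± 9.07 FPKM (1.5, SE 0.14, adjusted p = 0.00022), GDF15 to 240 ± 35.8 (1.21, SE 0.15), BTG2 to 22.3 (1.06, SE 0.16) and TP53I3 from 2.57 to 11.5 (1.81, SE 0.34). The p53 targets had 3 higher and 0 lower of 24 (relative 5 and 0, adjusted p = 0.0135, and 0.866 with an estimated correlation). CXCL8 fell to 8.77 ± 5.18 FPKM (−2.95, SE 0.37), HBD to 57.7 ± 15.7 (−1.62, SE 0.18) and HBA2 by log2 0.77 (SE 0.14), and 4 of 8 erythroid genes fell with 0 higher on both scales (adjusted p = 0.0052, and 0.727 with an estimated correlation). Oxidative phosphorylation had 10 of 45 lower (adjusted p = 0.0135, 0.318 on the relative scale and 0.952 with an estimated correlation). In all 293 genes rose and 1181 fell (relative 839 and 863), and no other of the 10 splits gave more than 2 genes. The 1474 calls became 718, 895 and 571 without DMSO replicate 1, 2 and 3.

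Between 100 and 1000 nM XG1 lost mitotic transcripts. AURKB fell from 225 ± 16.2 to 80.7 ± 9.50 FPKM (log2 −1.47, SE 0.13, adjusted p = 0.0010, relative −1.48). Of 50 G2/M genes 12 fell further (36 over the list alone, relative 19; adjusted p = 9.4e-36; 0.259 with an estimated correlation), as did 5 of 50 replication genes (18 over the list alone, relative 8; 1.1e-15; 0.402 with an estimated correlation). Histone genes had 2 of 25 lower (relative 3, adjusted p = 1.5e-05, and 0.402 with an estimated correlation). The homologous recombination (adjusted p = 0.0029), MYC (0.013) and immediate-early lists (up, 0.023, and 0.066 on the relative scale) passed with 0 members changed on the deposited scale, each with 0.917 with an estimated correlation. In all 8 genes rose and 38 fell. The 46 calls became 10, 4 and 82 without 100 nM replicate 1, 2 and 3, and 2 and 5 without 1000 nM replicates 2 and 3.

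The responses of the lines differed most in cell division and amino acid stress genes, which fell further in AMO1. At 1000 nM the response of RRM2 in XG1 minus that in AMO1 was log2 3.97 (SE 0.21, adjusted p = 4.6e-09, relative 3.33): XG1 fell from 47.9 ± 1.5 to 25.4 ± 0.48 FPKM (−0.89, SE 0.14, adjusted p = 0.0022). CTH fell in AMO1 and stayed at 16.8 ± 2.08 and 17.5 ± 1.06 FPKM in XG1 (difference 4.06, SE 0.22, adjusted p = 5.3e-09, relative 3.58). CHAC1 differed by 3.38 (SE 0.30), CDC6 by 3.43 (SE 0.23) and CDK1 by 2.88 (SE 0.23). UBE2C differed by 3.82 (SE 0.56) but was nearly absent from XG1 in DMSO. Of 50 replication genes 48 differed in this direction and 0 in the other (relative 46; adjusted p = 8.6e-24), of 50 G2/M genes 47 (relative 37; 6.9e-17), of 33 integrated stress response genes 27 (relative 23; 2.5e-11) and of 25 glycolysis genes 19 (relative 16; 1.4e-06). LDHA differed by log2 2.0 (SE 0.31). With an estimated correlation these 4 lists had adjusted p = 0.134, 0.240, 0.299 and 0.518.

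CCND3, the cyclin D of lymphoid cells, moved in opposite directions at 1000 nM. It rose in XG1 from 125 ± 11.2 to 188 ± 15 FPKM (log2 0.59, SE 0.13, adjusted p = 0.0096) and fell in AMO1 from 51.9 ± 1.78 to 13.6 ± 1.06 (−1.86, SE 0.18, adjusted p = 1.4e-06; difference 2.45, SE 0.18). The quiescence factor KLF2 fell in AMO1 from 173 to 29.8 FPKM (−2.63, SE 0.33) and stood at 7.22 ± 2.25 and 17.6 ± 3.73 in XG1 (1.2, SE 0.29, adjusted p = 0.0163; difference 3.82, SE 0.48). The XG1 call for KLF2 was lost without DMSO replicate 1 (adjusted p = 0.0661) or 1000 nM replicate 1 (0.0595) or 2 (0.0512). NF-kB targets lay low in the XG1 response only against the other genes, whose median difference was log2 0.545. On the deposited scale 3 were higher and 4 lower of 26 (relative 0 and 10; adjusted p = 0.00021; 0.518 with an estimated correlation). CXCL8 differed by −2.53 (SE 0.44) but was at the floor in AMO1. Erythroid genes had 3 of 8 lower (adjusted p = 4.2e-05; 0.063 on the relative scale and 0.117 with an estimated correlation), with HBD at −2.27 (SE 0.54). In AMO1 in DMSO these genes were low (HBG1 0.941, HBA2 0.329 and HBD 5.28 FPKM). They could hardly fall there, so this difference mainly restates their fall in XG1. In all 4198 genes of 12792 had a higher and 192 a lower log2 change in XG1 than in AMO1 (relative 1286 and 871).

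At 100 nM cell division and amino acid stress genes again fell further in AMO1. CTH differed by log2 3.17 (SE 0.22, adjusted p = 8.3e-07, relative 3.01), CHAC1 by 2.95 (SE 0.30), the spindle assembly factor TPX2 by 2.36 (SE 0.21), the helicase subunit GINS2 by 2.25 (SE 0.26), CDK1 by 2.19 (SE 0.23) and CDT1 by 2.11 (SE 0.20). Replication genes differed in 37 of 50 cases and G2/M genes in 38 of 50, 0 in the other direction (relative 39 and 40; adjusted p = 4.0e-32 and 3.4e-36; both 0.0558 with an estimated correlation). Of 33 integrated stress response genes 20 differed (relative 21; adjusted p = 4.0e-14; 0.232 with an estimated correlation). The histone gene HIST1H2BH differed by log2 4.81 (SE 0.78), with XG1 from 0.817 to 23.6 ± 18.6 FPKM, and SCO2, with its overlaps, by −3.36 (SE 0.68). In all 687 genes had a higher and 110 a lower log2 change in XG1 than in AMO1 (relative 803 and 417). The 797 calls became 472, 430, 482 and 470 without XG1 DMSO replicate 2, AMO1 DMSO replicate 2, AMO1 100 nM replicate 1 and AMO1 100 nM replicate 2.

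Most genes that changed at 100 nM changed at 1000 nM too. In XG1 193 genes rose and 833 fell at both doses, against 10.8 and 155.8 for independent calls, and the log2 changes correlated at 0.764 (0.494 in simulated data without any response). In AMO1 183 rose and 3077 fell at both, against 7.21 and 2036 (correlation 0.880, simulated 0.502). The doses share their 3 DMSO libraries, which could not be divided between them. The shared controls therefore add to each correlation and may add to each overlap. Simulated data without any response gave on average 0.01 genes called at both doses in XG1 and 0.02 in AMO1. What the shared controls add where genes do respond was not simulated. Between the lines, which share no library, 67 genes rose and 1378 fell in both at 1000 nM of 9648 tested in both, against 7.02 and 975.8 for independent calls, and 89 went in opposite directions (correlation 0.518). Relative to the median gene 545 rose and 826 fell in both, against 211 and 280.6. At 100 nM 62 rose and 746 fell in both (independent 5.33 and 333.8), 13 went in opposite directions and the correlation was 0.426. GDF15 at 1000 nM and POLR2A at 100 nM were among the genes that rose in both lines, and CDT1, PSAT1 and ASNS among those that fell.

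In AMO1 at 1000 nM the transcripts of the target complex fell on the deposited scale alone. CDK7 itself fell in AMO1 at 1000 nM from 16.9 to 6.86 FPKM (log2 −1.19, SE 0.19, adjusted p = 0.00011), but not relative to the median gene (−0.30, adjusted p = 0.183). Its partners MNAT1 and CCNH fell by log2 1.11 (SE 0.27) and 0.85 (SE 0.24), against relative changes of −0.25 and, in the other direction, 0.07. At 100 nM in AMO1 CDK7 had log2 −0.57 (adjusted p = 0.0360), against −0.158 relative to the median gene (0.528). The deposited-scale call was lost with replicate numbers as a block (0.0843) and in the fit of all 18 libraries (0.126). That call was lost without any 1 of the 6 libraries, with adjusted p = 0.0685, 0.0870 and 0.140 without DMSO replicate 1, 2 and 3 and 0.0855, 0.0685 and 0.15 without 100 nM replicate 1, 2 and 3. In XG1 CDK7 did not pass at 100 nM (−0.93, adjusted p = 0.068) or 1000 nM (−0.45, 0.35), nor did CCNH (0.067 and 0.91) or MNAT1 (0.063 and 0.54). Without 100 nM replicate 1 of XG1 the 100 nM values were 0.0090 for CDK7, 0.0382 for CCNH and 0.0088 for MNAT1, and with protein-coding genes alone 0.0265, 0.0267 and 0.0225.

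MYC, the growth regulator, fell in AMO1 from 82.2 ± 6.94 to 16.2 ± 9.67 FPKM at 1000 nM (log2 −2.46, SE 0.35, adjusted p = 4.0e-05, relative −1.54, adjusted p = 0.0018) and to 34.1 at 100 nM (−1.25, adjusted p = 0.0148, relative −0.82, 0.055). In XG1 it fell from 116 ± 16.2 to 47.7 ± 20.9 at 100 nM (−1.36, SE 0.32, adjusted p = 0.0196; relative −1.17, 0.061), a call lost without DMSO replicate 1 (0.0634) or 3 (0.0742), and did not pass at 1000 nM (−0.72, 0.147). IRF4 fell in AMO1 to 24.4 ± 5.77 FPKM at 1000 nM (−1.65, SE 0.21, adjusted p = 1.6e-05, relative −0.70) and to 44.8 at 100 nM (−0.78, 0.0128), the latter lost without DMSO replicate 2 (0.0648) or 100 nM replicate 2 (0.0569). E2F1, which drives S phase genes, fell in AMO1 by log2 3.61 (SE 0.25) and 2.10 (SE 0.25) at 1000 and 100 nM. In XG1 it fell at 1000 nM (−0.88, SE 0.20, adjusted p = 0.0134), a call lost without DMSO replicate 3 (0.0630) or 1000 nM replicate 2 (0.0637) or 3 (0.0532). At 100 nM it did not pass (0.092).

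CDKN1A, the cell cycle inhibitor induced by p53, did not change on the deposited scale in AMO1 at 1000 nM (162 to 164 FPKM, adjusted p = 0.945) but rose relative to the median gene (0.95, adjusted p = 4.7e-05). It did not pass in AMO1 at 100 nM (0.41) or in XG1 (0.14 at 100 nM, 0.46 at 1000 nM), although in XG1 at 100 nM it had 0.0495 without 100 nM replicate 1. MCL1, a survival factor of myeloma cells with a short-lived transcript, likewise held its level in AMO1 (940.3 to 823 FPKM, −0.23, adjusted p = 0.343) and rose relative to the median gene at both doses (0.74 at 1000 nM, 0.82 at 100 nM). In XG1 it did not pass (0.88 and 0.90). CCND1 fell in AMO1 at 1000 nM (−1.10, SE 0.20, adjusted p = 0.00029, relative −0.30, 0.075). The drug efflux pump ABCB1 did not pass on the deposited scale in AMO1 at 1000 nM (−0.30, adjusted p = 0.116) but had 0.39 on the relative scale (adjusted p = 0.0340). IRF4, CCND1 and ABCB1 were too low in XG1 to be tested against DMSO.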

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

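The tests of library exchange, of a share of other cells, of the scaling, of the low AMO1 library, of the taken amount of RNA and of the overlapping entries were chosen only after the result was seen. The counts over other splits of the samples were chosen before.

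What drew attention here was a difference between the lines in their response to the same dose, tested as the XG1 response minus the AMO1 response. At 1000 nM it held for 4390 genes. The division genes RRM2 (log2 3.97), CDC6 (3.43), UBE2C (3.82) and CDK1 (2.88) had a higher log2 change in XG1 than in AMO1. So did the cysteine and glutathione genes CTH (4.06) and CHAC1 (3.38), KLF2 (3.82), CCND3 (2.45) and LDHA (2.0). All of these genes fell in AMO1, and in XG1 they fell less, held or rose. CXCL8 (−2.53) and HBD (−2.27) had a lower log2 change in XG1. In AMO1 CXCL8 was at the floor and the erythroid genes were low, so these mainly restate the XG1 response. UBE2C was low in XG1 in DMSO (5.35 FPKM, against 1143 in AMO1), so it had little room to fall there. The lists were replication (adjusted p = 8.6e-24), G2/M (6.9e-17), integrated stress response (2.5e-11), glycolysis (1.4e-06), NF-kB targets (0.00021) and erythroid genes (4.2e-05). With an estimated correlation their adjusted p were 0.134, 0.240, 0.299, 0.518, 0.518 and 0.117.

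At 100 nM the responses differed for 797 genes. CTH (log2 3.17), CHAC1 (2.95), TPX2 (2.36), GINS2 (2.25), CDK1 (2.19), CDT1 (2.11) and HIST1H2BH (4.81) had a higher log2 change in XG1, and SCO2 (−3.36) a lower one. Of these the division, cysteine and glutathione genes fell further in AMO1. The lists were replication (adjusted p = 4.0e-32), G2/M (3.4e-36) and integrated stress response (4.0e-14), with adjusted p = 0.0558, 0.0558 and 0.232 with an estimated correlation.

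The scaling of the libraries alone does not account for the larger fall of the replication genes in AMO1, since 46 of 50 still differed relative to the median gene. Over all genes most of the one-sided difference followed the scaling. On the deposited scale 4198 genes had a higher and 192 a lower log2 change in XG1 than in AMO1, against 1286 and 871 relative to the median gene. With equal totals these counts were 835 and 1016. The AMO1 1000 nM library with the lowest total does not alone account for the line difference, since 3467 genes differed without it. The summed FPKM of AMO1 at 1000 nM, 39.64% of DMSO, cannot tell less RNA per cell from fewer cells or less RNA taken into those libraries, because the amount taken is not given in the sources used here. The size of the fall on the deposited scale therefore stays open. The values relative to the median gene have a factor common to all genes of a library divided out. The 2 sets of libraries thus responded differently to the same doses, and what in the cells made the difference was not tested.

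Over other splits of the samples, 4 of 100 gave a count as large as 4390 at 1000 nM, the real one included, and the highest other count was 5235. All 4 kept the real AMO1 groups, and no split with other AMO1 groups gave more than 44. At 100 nM it was 3 of 100, with the highest other at 1629, and again all 3 kept the real AMO1 groups, against at most 31 with other AMO1 groups. These counts follow the AMO1 response more than the XG1 grouping, so they say little about which XG1 libraries were treated.

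The libraries labelled XG1 carried erythroid genes and few plasma cell genes, as reported above. A small share of other cells in plasma cell cultures is argued against by the plasma cell genes of at least 100 FPKM in AMO1: their median XG1 level was 2.24% of AMO1, from 0.259% to 38.7% over 11 genes, with 5 under 1%. Single libraries exchanged between the lines are argued against too, since 0 of 18 libraries had the sign of the other line for erythroid minus plasma cell genes. The HBG1 values cannot tell another culture behind the label from the own state of the line. Either would put HBG1 above every AMO1 library, as was seen in 9 of 9 libraries. No reference profile of either line was used here, so this stays open. Until that is settled, the XG1 results describe the cells in those libraries and are an uncertain guide to myeloma.

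HNRNPH2 rose and RPL36A-HNRNPH2 fell in XG1 at 1000 nM. Reads of 1 locus assigned to either of the overlapping entries fit this: their sum changed by log2 −0.28 only, between 31.1 and 112 FPKM over all libraries. In 16 of 18 libraries 1 entry held more than 95% of the sum, and in 4 of 6 groups the replicates switched between entries. No biological explanation was tested.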

How the results depend on the processing

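The settings of protein-coding genes alone and of median-ratio factors without single libraries were chosen only after the result was seen. Single genes mostly kept their calls, and the counts moved more: 212 of 212 gene results kept direction and side of the threshold with other added constants, without the filter and with spike-in factors. With median-ratio factors 201 did (6 weaker, 1 stronger, 4 reversed), with equal totals 194 (7, 2 and 9), in 1 fit of all libraries 164 of 170, and with 1 library left out 1354 of 1386. Genes whose call failed without 1 library were mostly not named, so these shares describe the named genes alone. Because the values appear to have been rescaled to the spike-ins already, the result with spike-in factors says little about the scaling. Of 63 list results 58 held with median-ratio factors, 59 without the filter, 61 with another constant and 0 with an estimated correlation. That left 0 lists in each comparison with DMSO, against 10 and 11 in XG1 and 14 and 13 in AMO1 at 1000 and 100 nM. In XG1 at 1000 nM the fry test gave adjusted p = 0.0014 for G2/M, 0.0015 for replication and for ribosomal proteins and 0.0066 for erythroid genes. It did not pass for p53 targets (0.099) or immediate-early genes (0.29), which passed it relative to the median gene (0.00024 and 0.018). The cause was not tested for any change below unless named. Depth is not given in the sources used here, so what it limits was not measured.

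Median-ratio factors gave 108 genes between the XG1 doses, 614 between the AMO1 doses, and 2157 and 1220 for the difference between lines at 1000 and 100 nM. Equal totals gave 3064 genes in XG1 at 1000 nM, 219 and 488 between the doses in XG1 and AMO1, and 1851 for the line difference at 1000 nM. They also turned the main direction around. In XG1 at 1000 nM 2458 genes rose and 606 fell, against 436 and 1558 on the deposited scale. In AMO1 at 1000 nM 4569 rose and 1247 fell, against 264 and 6900. For the line difference at 1000 nM 835 had a higher and 1016 a lower log2 change in XG1 than in AMO1, against 4198 and 192. By construction equal totals remove the change in total and median-ratio factors the shift of the median gene. With median-ratio factors and without the AMO1 1000 nM replicate 2 there were 4491 genes in AMO1 at 1000 nM and 385 between its doses. With the same factors there were 118 between the XG1 doses without XG1 100 nM replicate 2, and without both libraries 2112 and 1378 for the line differences. Robust variance gave 79, protein-coding genes alone 103 and all 18 libraries in 1 fit 94 between the XG1 doses, and no filter gave 1466 between the AMO1 doses.

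A fold of at least 2, which by construction keeps fewer genes, left 661, 493 and 20 in XG1 (1000 nM, 100 nM, between doses), 3831, 1067 and 371 in AMO1, 2668 for the line difference at 1000 nM and 4989 between the lines in DMSO. The overlaps became 292 between the XG1 doses, 1012 between the AMO1 doses, and 381 and 133 between the lines at 1000 and 100 nM.

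With 1 library left out the counts ran from 1047 to 1564 and 571 to 1876 in XG1 (1000 and 100 nM), 2 to 82 between its doses, 6067 to 7201 and 1812 to 2613 in AMO1, and 519 to 3437 between its doses. They ran from 3227 to 4771 and 430 to 1136 for the line differences.

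The replicate block gave 1740, 1250 and 46 genes in XG1, 6932, 2910 and 1461 in AMO1, 3760 and 513 for the line differences and 6627 in DMSO. It ended the oxidative phosphorylation call in AMO1 at 1000 nM (adjusted p = 0.0502) and the CDK7 call in AMO1 at 100 nM (0.0843). Libraries with the same number did not go together, however: their correlations ran from −0.04 to 0.16 in XG1 and −0.18 to 0.12 in AMO1, over 0.1 in 2 and 1 of 9 pairs each.

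The sign of the change reversed in AMO1 for genes that fell less than the total or held their level. With median-ratio factors CCNH had log2 0.067, CDKN1A 0.95, MCL1 0.74 and ABCB1 0.39, and without 1000 nM replicate 2 as well CCNH had 0.20, CDKN1A 0.99 and MCL1 0.78. With equal totals CDK7 had 0.060, CCNH 0.44, MNAT1 0.11, CDKN1A 1.34, MCL1 1.14, CCND1 0.023 and ABCB1 0.67, and at 100 nM CDK7 0.070 and CDKN1A 0.43. With equal totals CDK7 (adjusted p = 0.771, and 0.762 at 100 nM), MNAT1 (0.648) and CCND1 (0.914) did not pass, while CCNH did (0.0172). With median-ratio factors CCNH did not pass (0.732, and 0.301 without 1000 nM replicate 2). CDKN1A, MCL1 and ABCB1 had not passed on the deposited scale, so no called change was reversed there.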

Other observations

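The genes of the first paragraph were chosen only after the result was seen, as were the tests of a share of other cells, of the scaling and of the taken amount of RNA; the counts over other splits were chosen before.

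The globin genes of the libraries labelled XG1 came with the transcription factors that switch them on. In DMSO GATA1 stood at 30.9 ± 0.55 FPKM in XG1 and 0.0883 in AMO1, KLF1 at 99.6 ± 11.5 and 0.323, and NFE2 at 100.4 ± 9.56 and 0.205. The red cell ammonia channel RHAG was at 242 ± 23.6 and 0.166, and the embryonic globin gene HBZ at 212 ± 16.7 and 0.0904. The cell cycle inhibitor gene CDKN2A went the other way, at 0.456 in XG1 and 47.3 in AMO1, as did MTAP, which lies beside it, at 0.166 and 6.83. The tyrosine kinase gene ABL1 was at 85.9 ± 12.1 FPKM in XG1 and 6.11 in AMO1. Each of these genes separated all 9 XG1 from all 9 AMO1 libraries.

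Cells that make erythroid factors together with several globins may be erythroid throughout. The plasma cell genes of at least 100 FPKM in AMO1, at a median of 2.24% in XG1, are consistent with that and argue against a few red cell precursors among plasma cells. Which line the cells came from was not tested.

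The polymerase subunit gene POLR2A rose in both lines at 100 nM. In the AMO1 libraries at 1000 nM, where the total stood at 39.64% of DMSO, POLR2A still rose relative to the median gene (log2 1.58). Why it rose was not tested.

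For the comparisons with 10 splits of the samples, only the real split reached its count, 1 of 10 each, too few splits for a share under 0.05, so this count alone cannot tell chance from a real difference. In XG1 the counts were 1994 at 1000 nM (highest other 3), 1474 at 100 nM (2) and 46 between doses (3). In AMO1 they were 7164 (2), 3386 (4) and 2482 (6), and between the lines in DMSO 8292 (0). For lists the counts were 10 (highest other 9) and 11 (8) in XG1 at 1000 and 100 nM, and 14 (12) and 13 (12) in AMO1. The number of lists past the threshold was nearly reached by other splits with the preset correlation. Every other split kept most libraries of each group together, so part of a difference between the groups stayed in it. The mixing also widened the spread within groups, against which single genes are tested. The counts of other splits are therefore no measure of what chance alone would give.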
